A study of Mus musculus with 2 samples.

How the data were processed

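Total RNA of hearts from B6CASTF1/J male mice, an F1 cross of the B6 and CAST mouse strains, was sequenced after ribosomal RNA reduction at an age of 36 days. Per the labels, 300 ng of RNA entered each stranded library and ERCC spike-ins, synthetic RNAs of known sequence, were added. The labels give 1 group with 2 biological replicates, as separate biosamples with the same donor entry, and whether that entry stands for 1 animal is not given in the sources used here. No groups were compared. Replicates 1 and 2 held 41846500 and 42481600 expected counts, of which 203838 and 199815 fell on spike-ins.

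Expected counts per gene and per transcript were deposited by the authors in a first quantification, made per the sample notes from alignments to the transcriptome on mm10 with the GENCODE annotation M21. TPM and FPKM values were deposited by the authors beside these expected counts, scaled over all listed entries with the spike-ins included. The percent of a gene's TPM held by each transcript was also deposited by the authors. Estimated counts and TPM per transcript of a second quantification, made directly from the reads and an index per the sample notes, were deposited by the authors as well, and were summed per gene. The column layouts are those of RSEM and kallisto, and the tools and versions are not given in the sources used here. Per the file headers and values, the effective length in the first quantification is the transcript length minus 99 nt. The second quantification takes off more, which corresponds to mean fragment lengths of 326 and 328 nt. Per gene, the effective length is a weighted mean over transcripts.

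Gene names, classes and positions were taken from the GENCODE M21 annotation, and positions are given on mm10 counted from 1. Expected counts were rounded to whole numbers for edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3. TMM factors were computed without spike-ins and numbered tRNA entries after edgeR's expression filter. The log2 ratio of replicate 2 over replicate 1 used TMM-scaled expected counts with a prior count of 1, and its 95% interval is an exact Clopper-Pearson interval on the 2 counts. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, or 0.0717 and 0.0706 CPM in replicates 1 and 2.

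Genes were called different at a mean expected count of 50 or more and a ratio of 2-fold or more. This is a rule of size, not a test, since an exact sign permutation over 2 hearts cannot go below p = 0.5. Each fixed gene list was described by the median log2 ratio of its members with a mean expected count of 10 or more. That median was ranked among 10000 random lists of the same size drawn from the same 20 bins of mean expression, and lists below percentile 2.5 or above 97.5 are said to stand apart. Lists with under 3 measured members were not ranked. The rank describes these 2 libraries.

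The lists, the pairs, the rule for named genes and most alternatives were fixed before the data were examined. Named are the 20 nuclear protein-coding genes of highest mean TPM, the mitochondrially encoded protein genes, the 10 most abundant noncoding genes of 200 nt or longer, members of fixed lists and pairs, the 10 genes with the largest ratio in each direction, and the 10 with the largest difference between quantifications. Any other gene was chosen after its values were seen. Results for some genes that this rule names are not reported here. Alternatives covered detection thresholds, units, scalings, count filters, matching of random lists, fold thresholds, the second quantification and each library alone.

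The rules were tested on simulated data. In simulated libraries of 15749 genes, replicate 2 against replicate 1, genes changed 4-fold gave a median absolute log2 ratio of 2.00 and those changed 2-fold gave 1.01. The 2-fold rule called 100% of genes changed 4-fold, 50% of those changed 2-fold, which lie at its threshold, and 0.0968% of unchanged genes. Of 200 simulated lists without a change, 3% stood apart. Of 50 lists of 12 genes moved by 0.3 on the log2 scale, 88% did. These rates need not hold for the real lists, whose members can move together. edgeR's dispersion estimate was checked on simulated counts for 15103 genes, where a coefficient of 0.15 came back as 0.149.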

Results

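Total RNA of the heart was sequenced in male B6CASTF1/J mice aged 36 days, as 1 group with 2 biological replicates, called hearts here. The libraries held 41846500 and 42481600 expected counts in the first quantification. Levels are given as mean ± SD over the replicates (n = 2 throughout), and ratios as log2 of replicate 2 over replicate 1.

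Genes of heart muscle contraction and of blood were among the most abundant nuclear protein-coding genes. Myh6, the adult cardiac myosin heavy chain (chromosome 14, 54941921 to 54966927), was the most abundant nuclear protein-coding gene in the first quantification at 8077 ± 617 TPM, while the second put Myl2 first at 13936 TPM and Myh6 at 7523 TPM. The oxygen carrier Mb followed at 6458 ± 373 TPM, and Myl2, the ventricular light chain, at 6399.5 ± 401 TPM in the first. Actc1, the cardiac actin, stood at 4917 ± 375 TPM and Tpm1, a tropomyosin, at 4341 ± 60.5 TPM. The calcium pump Atp2a2 reached 4138 ± 329 TPM and its inhibitor Pln 2134 ± 125 TPM. Troponin genes Tnni3 and Tnnt2 stood at 3513 ± 125 TPM and 3087 ± 192 TPM. Among the 20 most abundant nuclear protein-coding genes, 8 belonged to the sarcomere list of 24 genes. The haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 stood at 5287 ± 2691 TPM, 4439 ± 2343 TPM and 4362 ± 2319 TPM. In the second quantification Hba-a1 at 9972 TPM and Hbb-bs at 9030 TPM were above Mb at 8181 TPM and Myh6, with the split between near-identical copies uncertain. The sarcomere list held 11.9% ± 0.589 of nuclear protein-coding TPM.

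Energy metabolism genes were abundant too. The ATP synthase subunit Atp5b stood at 3369 ± 33.9 TPM, the fatty acid binding protein Fabp3 at 2254 ± 215 TPM, and Lpl, which releases fatty acids from lipoproteins, at 1292 ± 26.2 TPM. All 21 fatty acid oxidation genes and all 23 nuclear oxidative phosphorylation genes reached 1 TPM in both hearts. Among cardiac transcription factors, 15 of 16 did, with Nkx2-5 at 29.0 ± 1.15 TPM and Gata4 at 31.3 ± 3.19 TPM. Hand1 had 0 counts in both libraries, which allows up to 0.0717 and 0.0706 CPM (counts scaled to the library total). Y-linked Ddx3y had 2854 and 3054 counts in replicates 1 and 2, and Xist, the RNA of the inactive X chromosome, 5 and 2.

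The reads fell into a few large classes. Nuclear protein-coding genes took 58.8% ± 0.853 of expected counts and mitochondrially encoded protein genes 10.7% ± 0.424. Loci of ribosomal RNA and rRNA-like sequence took 23.3% ± 1.34, most of it from the mitochondrial ribosomal RNA mt-Rnr2, with 7449024 and 6956298 counts. Small RNA took 2.67% ± 0.0312 of expected counts, but 16.9% of TPM and 0.00405% of estimated counts in the second quantification. By TPM, nuclear protein-coding genes took 37.8%. Among mitochondrially encoded protein genes mt-Co1, a cytochrome c oxidase subunit, was highest at 35881 ± 1752 TPM and mt-Co2 was lowest at 606 ± 19.3 TPM. The pseudogenes Gm28661, Gm29216, Gm10925 and Gm28437 lie side by side on chromosome 1, and the lengths of Gm28661, Gm10925 and Gm28437 are close to those of mt-Co2, mt-Atp6 and mt-Co3. Such near copies can take mitochondrial reads, although the sequences were not compared here. Values of mt-Co1, mt-Co2, mt-Co3 and mt-Atp6 and the share of mitochondrially encoded protein genes are therefore uncertain. Pseudogenes took 3.41% ± 0.0698 of expected counts, Gm28661 alone 39.3% and 41.0% of that in replicates 1 and 2. In the second quantification mt-Co2 stood at 3696 TPM. In all, 10943 of 22015 nuclear protein-coding genes reached 1 TPM in both hearts, and 331 of 13371 lncRNA genes did. Malat1 was the most abundant lncRNA without rRNA-like sequence among the named genes, at 1202 ± 71.5 TPM.

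**Figure D1:**
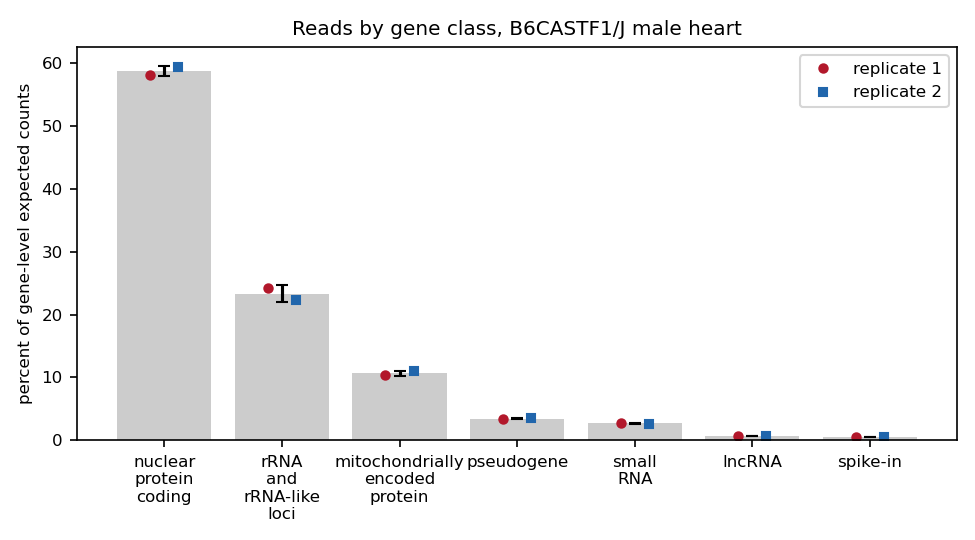
Percent of gene-level expected counts (y axis) per gene class (x axis), with bars for means, error bars for the SD (n = 2), circles for replicate 1 and squares for replicate 2. Nuclear protein-coding genes hold 58.8% on average.

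Shares of TPM within fixed gene pairs showed which member was more abundant. Myh6 held 91.1% ± 0.00940 of the TPM of Myh6 and Myh7, the slow and fetal myosin. Tnni3 held 99.99% ± 0.00224 against the fetal Tnni1, and the cardiac pump Atp2a2 99.99% ± 0.000599 against the skeletal Atp2a1. Actc1 took 93.0% ± 3.62 against the skeletal actin Acta1, and Myl2 96.6% ± 0.930 against the atrial Myl7. In glucose handling, the insulin-responsive transporter Slc2a4 took 97.6% ± 0.0319 against Slc2a1, and Ldhb 77.0% ± 1.68 against Ldha. Cpt1b took 89.2% ± 0.0308 against Cpt1a, the liver form of the enzyme that admits fatty acids into mitochondria. Igf2, the fetal growth factor, held 82.5% ± 0.0406 against Igf1. The first gene held the larger share in 18 of 20 pairs. The exceptions were Col1a1 with 29.5% ± 0.832 against Col3a1, both collagens, and the clock gene Arntl with 42.4% ± 28.2 against Dbp. The Arntl share was 62.4% in replicate 1 and 22.5% in replicate 2, and 56.7% on average by expected counts, so it leads or not by library and unit. Acta1 differed between the hearts, at 493 and 242 TPM, a log2 ratio of -1.07 with a 95% counting interval of -1.10 to -1.03. No test of these shares is given, as an exact sign permutation over 2 hearts cannot go below p = 0.5, and the Myh6 share was 81.9% in the second quantification.

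**Figure D2:**
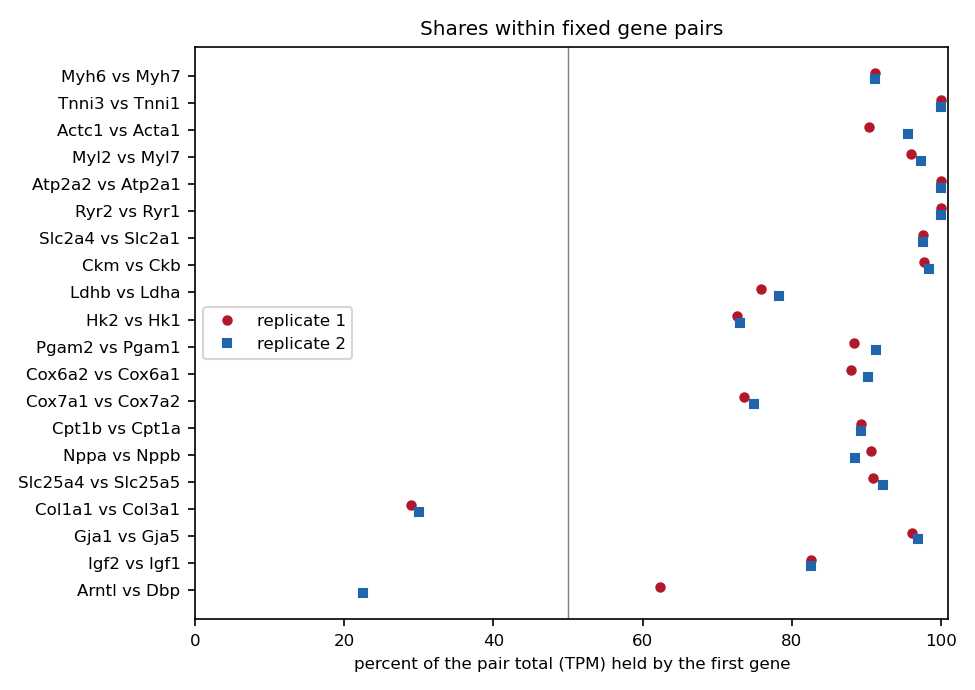
Percent of the TPM of each fixed gene pair held by its first gene (x axis), with circles for replicate 1, squares for replicate 2 and a line at 50%. Myh6 lies at 91.2% and 91.1%.

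Gene levels were close between the hearts. Across 15749 genes with a mean expected count of 10 or more, log2(TPM + 1) gave a Pearson correlation of 0.991 and a Spearman correlation of 0.986. Genes are not independent replicates, so no p is given. Of 12541 genes with a mean expected count of 50 or more, 95.7% differed by less than 1.5-fold. A check for a library deposited more than once gave a chi-square of 22.0 per degree of freedom, set against counting error alone. edgeR's biological coefficient of variation was 0.119 over 15103 genes, from 0.174 at low to 0.0921 at high abundance.

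Fat cell markers and single genes of lipid synthesis were among the genes furthest toward replicate 1. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 1635 and 46 counts in replicates 1 and 2, a log2 ratio of -5.17 with a 95% counting interval of -5.65 to -4.77. The desaturase Scd1 stood at -4.54 (-4.63 to -4.45) and the fatty acid synthase Fasn at -3.89 (-3.96 to -3.82). Plin1, which coats lipid droplets of fat cells, stood at -3.89, Pck1, an enzyme of glucose and glycerol synthesis, at -3.87, and the fatty acid elongase Elovl6 at -3.78. Cdo1 at -3.42 and Otop1 at -4.50 were also among the 10 genes furthest toward replicate 1. All 6 measured adipocyte markers were at least 2-fold higher in replicate 1, among them Adipoq at -2.88 and Cidec at -3.26.

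Toward replicate 2, the clock output gene Dbp stood at 1.92 (1.71 to 2.16) with 207 and 813 counts. The chemokine receptor Cx3cr1 stood at 1.75, and the interferon-induced Ifit3 at 1.82. Gm28635 stood at 1.75. In all, 126 genes were 2-fold or more higher in replicate 1 and 35 in replicate 2, or 1.28% of 12541 genes. Both quantifications gave 2-fold or more in the same direction for 108 and 18 of them. The pseudogenes Gm6361, Gm6565, Gm13394 and Gm10146 and the genes 1700047I17Rik2, Hist1h2ai and Chtf8 also rank among the largest ratios. Of these, only Gm6565 kept a 2-fold ratio in the same direction in the second quantification, on 0 and 7.03 reads. All are uncertain, since the first quantification could split reads between copies or overlapping genes.

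**Figure D3:**
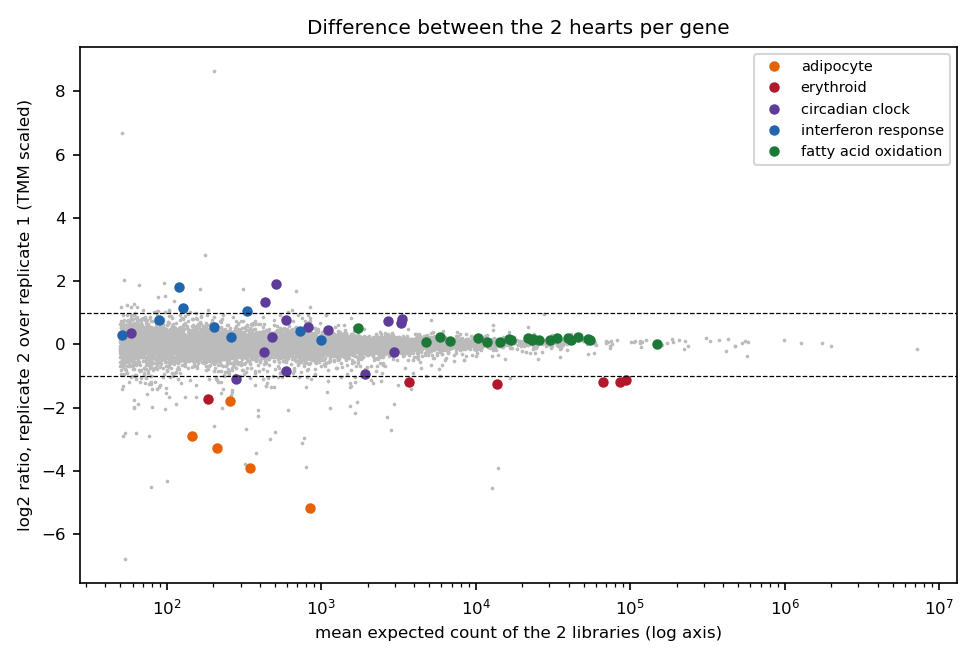
Log2 ratio of replicate 2 over replicate 1 (y axis) against mean expected count (log x axis) for genes with a mean count of 50 or more, with members of 5 fixed lists in colour and dashed lines at 2-fold. Scd1 is among the grey points at -4.54.

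Of 35 ranked gene lists, 14 stood apart between the hearts, where 1.75 would be expected if the members of each list varied independently. Members of a list can move together between any 2 samples, and some lists share members, so 14 against 1.75 is no test. Blood genes were higher in replicate 1. The erythroid list had a median log2 ratio of -1.19 (central range of random lists -0.11 to 0.13), with 6 of 7 members at 2-fold or more. The haemoglobin genes Hbb-bs and Hba-a1 stood at -1.13 and -1.19, and Alas2, an enzyme of haem synthesis in red cells, at -1.19. Hba-a1 and Hba-a2 are near-identical and their split is uncertain, as is that of Hbb-bs and Hbb-bt. The adipocyte list stood at -3.07 (central range of random lists -0.26 to 0.21).

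Immediate early genes, which respond within minutes to stimuli, were mostly higher in replicate 1. Their median was -0.67 (central range of random lists -0.12 to 0.099), with Nr4a1 at -3.13, Fos at -1.87, Atf3 at -1.53 and Zfp36 at -1.35, while Egr1 stood at 0.23. Within the heat shock list, which did not stand apart, Hspa1b, a near copy of Hspa1a whose split is uncertain, was 3.99-fold higher in replicate 1. Clock genes split. The list median was 0.46 (central range of random lists -0.093 to 0.079), with Dbp at 1.92, Per3 at 1.36, Tef at 0.79 and Nr1d1 at 0.74, and with Arntl at -0.84, Npas2 at -1.10 and Per1 at -0.93. All 11 interferon response genes were higher in replicate 2, with a median of 0.76 (central range of random lists -0.19 to 0.18), including Ifit3 at 1.82, Usp18 at 1.49 and Irf7 at 1.15.

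Metabolic and muscle lists moved by less. All 21 fatty acid oxidation genes were higher in replicate 2, with a median of 0.16 (central range of random lists -0.023 to 0.07), from Lpl at 0.0064, which was below 0 in the second quantification, to Ucp3 at 0.51. The sarcomere list stood at 0.089 (central range of random lists -0.017 to 0.069), with Tcap at 0.40 and Acta1 at -1.07. Calcium handling and ion channel genes stood at 0.071 (central range of random lists -0.035 to 0.068), a call lost in the second quantification. Glycolysis and glucose uptake stood at -0.053 (central range of random lists -0.037 to 0.073), with Eno1 at -0.69, and its median turned to 0.021 under spike-in scaling. Imprinted genes stood at -0.22 (central range of random lists -0.092 to 0.09), with H19 at -1.15 and Igf2 at -0.43.

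Markers of other cell types and chambers moved as well. Atrial genes were lower in replicate 2 at -0.24 (central range of random lists -0.091 to 0.086), with Myl7, Myl4 and Sln at -0.50, -0.44 and -0.50, while Nppa was at -0.023. The 7 ventricular genes were all higher in replicate 2, and their median of 0.11 (central range of random lists -0.12 to 0.13) did not stand apart. Fibroblast markers stood at -0.34 (central range of random lists -0.08 to 0.09), with Col3a1 at -0.46 and Postn at -0.57 against Dcn at 0.0042. Mesothelial and epicardial markers stood at -0.43 (central range of random lists -0.22 to 0.20), with all 6 higher in replicate 1. Lymphocyte markers stood at 1.04 (central range of random lists -0.64 to 0.62) over 4 members with few reads, Cd79a with 18 and 43 counts, a call lost in the second quantification. Endothelial markers were at -0.011 (central range of random lists -0.057 to 0.073), with Kdr at 0.43 and Aqp1 at -0.22, and did not stand apart, and their median changed sign under library totals and spike-in scaling. Nor did macrophage markers at -0.079 (central range of random lists -0.11 to 0.089), among which Csf1r stood at 0.075 and Cx3cr1 at 1.75.

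Thymus, lung epithelium, liver and skeletal muscle markers had few reads. Of the thymus, lung epithelium and liver markers, 0 reached 1 TPM in both hearts, and Alb, the main plasma protein of liver, had 1 and 0 counts. Among skeletal muscle markers 1 did, Tnni2 at 1.18 ± 0.113 TPM. Lung epithelium, liver and X inactivation lists had too few measured members to rank. The lists for conduction system, cardiac transcription factors, nuclear oxidative phosphorylation, mitochondrially encoded genes, cell cycle, Y-linked genes, rRNA-like loci, noncoding RNA, isoform genes, fetal and stress genes did not stand apart, nor did heat shock genes. Neither did those for endocardial, lymphatic endothelial, pericyte and smooth muscle, neutrophil, Schwann and neuronal, skeletal muscle and thymus markers. The medians of the lists inside the random range ran from -0.26 for Schwann and neuronal to 0.11 for ventricular genes.

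**Figure D4:**
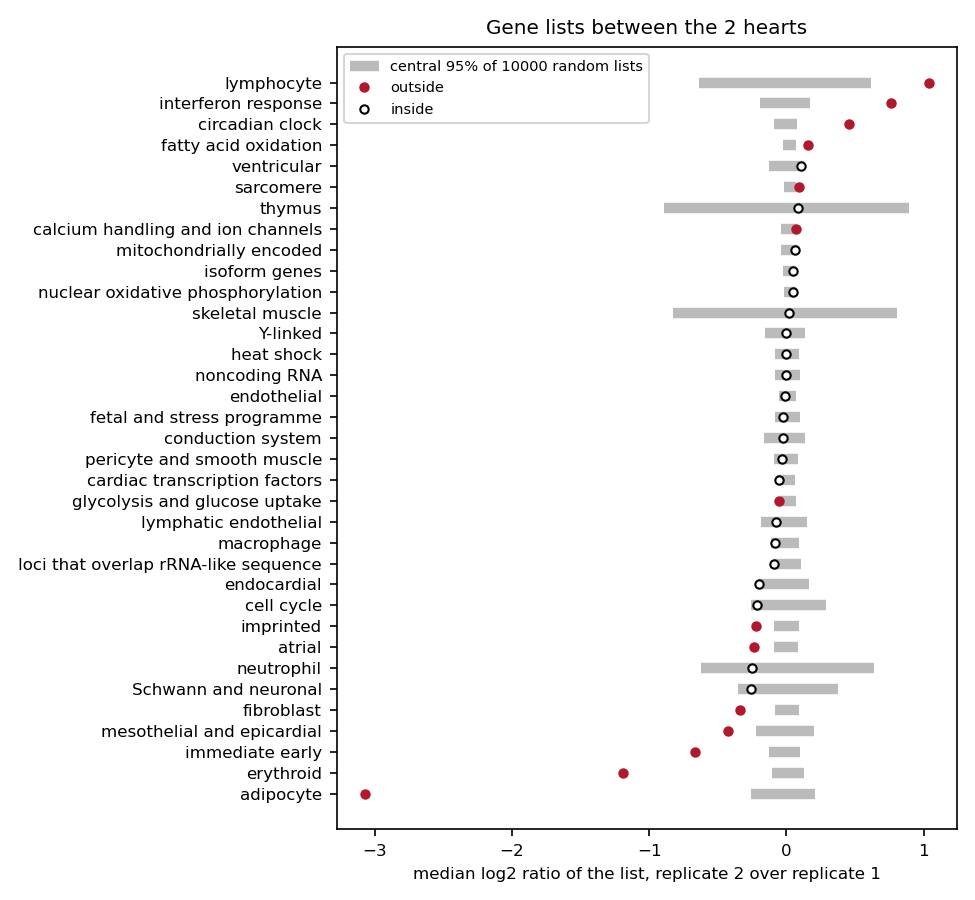
Median log2 ratio of replicate 2 over replicate 1 (x axis) per gene list (y axis), with grey bars for the central 95% of 10000 random lists of matched expression, filled points outside it and open points inside. The adipocyte list lies at -3.07 and the lymphocyte list at 1.04.

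Each heart used the same main transcript for all 21 genes of the isoform list. Mybpc3, myosin-binding protein C, kept 99.4% ± 0.0566 of its TPM in Mybpc3-203 and Tpm1 97.0% ± 0.0212 in Tpm1-205. Atp2a2-202 held 75.6% ± 0.247 and Ryr2-201, of the calcium release channel, 81.8% ± 0.283. Ttn, the giant spring protein of the sarcomere, was spread further, with 36.7% ± 1.10 in Ttn-201. Camk2d-202 held 43.7% ± 4.88. The second quantification named the same main transcript in both libraries for 14 of the 21. The genes for which it named another included Tnnt2, Pkm, Cacna1c and Slc8a1 in both libraries, and Mef2c and Nebl in 1 library, so the main transcript of these genes is uncertain. Across 7016 genes with several transcripts and a mean of 5 TPM or more, the libraries shared the main transcript for 91.7%. The quantifications shared it for 75.3% in replicate 1 and 75.5% in replicate 2.

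Several short RNAs and pseudogenes differed widely between the quantifications. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, stood at 69995 ± 129.9 TPM each in the first and at 0.230 TPM in the second, and their split is uncertain. Rn7sk, a regulator of transcription elongation, was at 14985 and 0.982 TPM, and Rpph1, the RNA of ribonuclease P, at 3146 and 2.73 TPM. The mitochondrial mt-Nd4l was at 8683 and 217 TPM, and mt-Atp8, at 4399 in the first, was near 0 in the second. Longer pseudogenes were also among the 10 genes furthest apart. Gm10925 was at 12061 TPM in the first and 0.000757 TPM in the second, and Gm28439 was listed at 0 in the first and at 1307 TPM in the second. Of 8589 genes with 5 TPM or more in either, 274 were 4-fold or more lower in the second and 93 higher. The lower ones included 113 small RNA genes and 130 pseudogenes. Across 55450 genes log2(TPM + 1) gave Pearson correlations of 0.960 and 0.961 in replicates 1 and 2, with 26472 of the genes at 0 in both. Across 141767 transcripts they were 0.796 and 0.796. These correlations rest partly on the genes at 0, and over genes at 5 TPM or more in either, a filter chosen after the data were seen, they were 0.785 and 0.788. Over transcripts filtered alike they were 0.337 and 0.336.

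**Figure D5:**
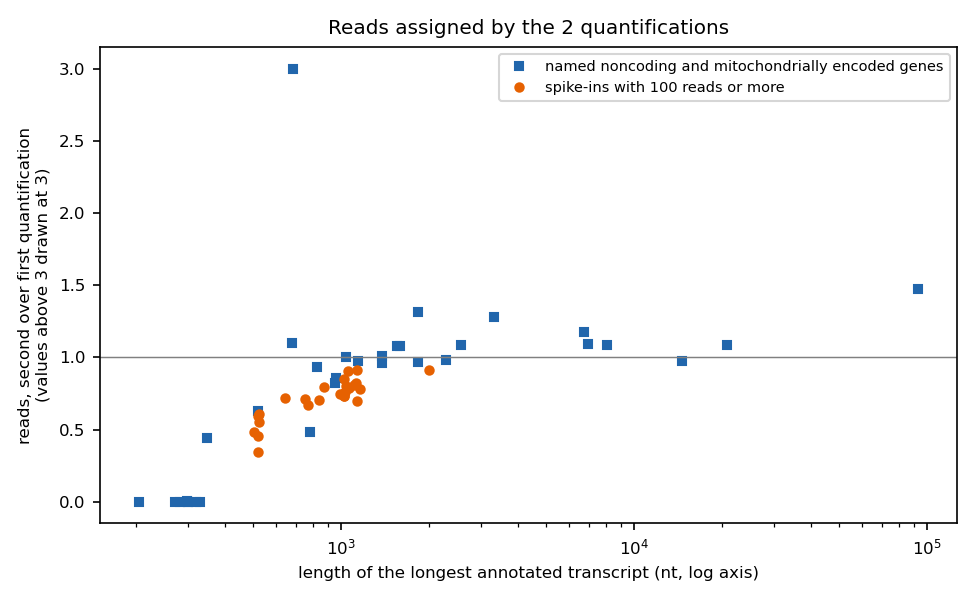
Reads in the second over the first quantification (y axis) against the length of the longest transcript (log x axis), with squares for named noncoding and mitochondrially encoded genes, circles for spike-ins with 100 reads or more, and values above 3 drawn at 3. Spike-ins of 900 nt or longer have a median ratio of 0.790.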

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

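Of the alternative values for the main results, 289 kept their side of the threshold or moved by less than the bound. Among these were lists inside the random range whose median changed sign. Thymus markers went from 0.084 to -0.16 in the second quantification, and cardiac transcription factors from -0.051 to 0.023 under spike-in scaling. Of the values for single genes, pairs and levels, 180 kept direction and side or moved within the bound. Most were FPKM shares, lone libraries or rescaled ratios, which could hardly change. Another 47 moved further without a change of direction. The levels of the 20 most abundant genes in the second quantification were 0.569 to 2.25 times those in the first. The count of genes differing 2-fold was 161, and 561 at a mean count of 10 or more, 83 at 200 or more, 535 at 1.5-fold and 57 at 3-fold, as stricter or looser rules take fewer or more genes. Other scalings, the second quantification and nuclear protein-coding genes alone gave 138 to 162. Settings chosen after the data were seen gave 126 in both quantifications and 145 without pseudogenes. At 5 TPM, 7174 nuclear protein-coding genes were detected. By TPM, nuclear protein-coding genes took 37.8%, mitochondrially encoded protein genes 14.1% and small RNA 16.9%. By estimated counts of the second quantification they took 61.9%, 10.2% and 0.00405%. The Myh6 share was 96.4% by expected counts and 81.9% in the second quantification. The Arntl share against Dbp, 42.4% on average, was 56.7% by expected counts, and 22.5% to 62.4% in a lone library. The correlation of the libraries was 0.976 with a pseudocount of 0.01.

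Of 14 lists apart, 12 stayed outside the random range in each of 7 settings, and lymphocyte markers had too few members at a mean count of 50. The settings that changed only the scaling shift a list and its random lists together, so they could hardly change a call. In the second quantification calcium handling (0.061) and lymphocyte markers (0.58) came inside the range, while cell cycle (-0.31) and rRNA-like loci (-0.099) left it. The rRNA-like loci also left it with lists matched on length (-0.089). Without members shared with another list, a setting chosen later, fetal and stress genes (0.26) and ventricular genes (0.27) left it. Glycolysis turned to 0.021 under spike-in scaling, which moved the median of all genes by 0.074, yet stayed outside. In the second quantification Gm13394 stood at -0.039, Hist1h2ai at -0.93 and Gm6361 at 2.93, each with its sign reversed, and 1700047I17Rik2, Gm10146 and Chtf8 came below 2-fold. The correlation of the quantifications across genes was 0.956 with a pseudocount of 0.1. At 5 TPM or more in either it was 0.786 across genes and 0.336 across transcripts, a filter that takes out the genes low in both. At 20 TPM or more, 178 genes differed 4-fold. Except where the rule itself gives it, the cause was not tested. A lone library lies within 1 SD of the mean of 2, so it is no check of the levels. Movement was judged at 0.01 for the correlation of the libraries and at 1.5 times for the coefficient of variation, which have no spread of their own, and the latter ranged from 0.116 to 0.145. No paired analysis was possible because the labels give 1 group.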

Other observations

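A list of lipid synthesis genes, Fasn, Scd1 and Elovl6 among them, was written after some of its values were seen. Of its 12 genes, 9 were 2-fold or more higher in replicate 1, and the list's median log2 ratio was -2.10. Acaca, the first enzyme of fatty acid synthesis, stood at -2.28, the mitochondrial citrate carrier Slc25a1 at -2.97, and the sugar phosphate enzyme Tkt at -2.16. Acly, which cleaves citrate to acetyl-CoA, and Thrsp, whose values had not been seen, stood at -1.88 and -1.95. Me1 at -0.097, Acss2 at -0.28 and the regulator Srebf1 at -0.06 were below 2-fold.

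Tests of the fragment length, of missing sequences, of lipid synthesis in heart cells and of scaling for the adipocyte genes were chosen after the related values were seen, and the other tests before. No biological explanation of a group difference was tested, since the labels give 1 group.

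The short RNAs Rn7s1, Rn7sk, Rpph1 and mt-Atp8 were near 0 in the second quantification. All genes of 330 nt or shorter with 100 counts or more were listed there (100% of 66), which argues against missing sequences. Spike-ins have no mouse copies, yet 4 of 350 nt or shorter had a median ratio of 0, with 54 reads in the first quantification, 45 of them from 1 spike-in, and 0 in the second. This argues against shared reads as the whole cause, on few reads. Across 26 spike-ins the ratio rose with length (Spearman 0.827) and with the ratio of effective lengths (Pearson 0.881). All of these are 505 nt or longer, above the fragment length. Of the 66 short genes, Rn7s1, Rpph1 and mt-Atp8 among them, 65 kept under 10% of their counts in the second quantification. A limit at the fragment length is a candidate explanation, which among spike-ins rests on the few reads of the shorter ones.

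Adipocyte and lipogenic genes were higher in replicate 1. The scalings run move all genes alike by too little to decide. Under spike-in scaling the adipocyte list stood at -3.00, and the central range of random lists of the same expression began at -0.19. This argues against scaling or depth as the cause. Adipose tissue left on the heart of replicate 1 may contribute but stays undecided, because 8 adipose genes not seen before had a median of -0.68, between the bounds set beforehand. Of the 6 measured adipocyte markers, a list fixed before the data were examined, 100% were at least 2-fold lower in replicate 2. Adipoq and Ucp1 are no lipid synthesis genes, so a change of lipid synthesis inside the heart cells alone would leave them unaccounted for. These markers are part of the pattern itself and so no separate test of that explanation, and the 8 genes not seen before do not decide it. A wider change in the heart cells was not tested. Of the 8 genes only 2 were at least 2-fold lower in replicate 2. In replicates 1 and 2, Adrb3 had 82 and 4 counts and Elovl3 48 and 0. Plin4 at 0.21 and Pnpla2 at 0.05 were not lower. With 58.6 and 197 TPM in these hearts, Plin4 and Pnpla2 may be little moved by some adipose tissue, so their values do not count against it. The median of the 8 genes therefore cannot decide.

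Clock genes were apart between the hearts. The test used genes whose values had not been seen when it was chosen. Most of them are also in the fixed clock list and so give no separate support for it. The median of the Dbp-phase genes minus that of the Bmal1-phase genes was 1.18. Collection at another time of day or shifted clocks may account for this, and the labels give no time. Of the Dbp-phase genes 7 of 8 were higher in replicate 2, and Per1 at -0.93 went the other way. The medians had opposite signs, -0.62 for 3 Bmal1-phase genes and 0.57, which argues against scaling. The log2 ratio did not follow effective length (Spearman -0.0180). Loss of RNA quality stays undecided, because in total RNA after ribosomal RNA reduction it need not appear as a trend with length.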
